A study of Homo sapiens with 6 samples.

How the data were processed

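RNA from LS174T cells, a mucin-producing human colon adenocarcinoma line, was measured on 6 Affymetrix Human U133 Plus 2.0 arrays, 1 array per culture. The labels state triplicate cultures per condition: 3 received the vehicle DMSO and 3 received CompE at 250 nM, both for 48 h. The groups were taken from the sample titles. CompE is a name in common use for Compound E, an inhibitor of gamma-secretase, the protease that releases the intracellular part of Notch receptors; the labels give the abbreviation alone.

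Per the series design text and the labels' protocols, the authors amplified and labelled each RNA with biotin by in vitro transcription from the 3' end, hybridised it, and normalized the arrays against each other with dChip. The deposited values are probe set intensities on a linear scale, where 0 is the lowest value. Whether dChip used mismatch probes, and its version, are not given in the sources used here. The authors also stated that 10,896 probes of low variation between replicates were selected for their own analysis. That selection is not applied in the deposited table, which holds 54674 probe sets, and its exact rule is not given in the sources used here, so it was used as an alternative only.

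Intensities below 1 were set to 1 and log2 was taken. Between 0.768% and 0.902% of the values of an array lay below 1. No second normalization was applied, because the authors had already scaled the arrays. The 62 Affymetrix control probe sets were left out, as were the probe sets in the lowest 40% of mean log2 value over all 6 arrays (below 4.61, an intensity of 24.4), which left 32767 probe sets. Gene names came from the platform annotation of 2016: 41097 probe sets had 1 gene, 1800 had several, and 11721 were not listed in that annotation and are unnamed here. For 41043 of the probe sets with 1 gene the Entrez identifier was found in the reference gene table, and the symbol there was used; the remaining 54 kept the annotation's symbol. Only probe sets with 1 gene were tested (26962 past the filter). The probe set with the highest mean log2 value stood for its gene, which gave 14308 genes. Of the 6977 genes with more than 1 probe set past the filter, 3 (ESPN, FBRSL1 and RPAIN) had probe sets that passed in opposite directions when probe sets were tested in place of genes; none of the 3 is reported otherwise.

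CompE was compared with DMSO by limma (version 3.58.1, in R 4.3.3) with lmFit and eBayes, two-sided, on all 6 arrays and with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene is said to have risen or fallen where the adjusted p was under 0.05. A further count required a change of at least 2-fold. Fold changes are 2 to the power of the difference between the groups' mean log2 intensities and can understate true changes of dim genes. As a measure of background, the array's 27 probe sets for Bacillus transcripts, which human RNA does not hold, were used: the 95th percentile of their mean log2 values was 5.51, an intensity of 45.7. Where the dimmer group of a gene lay at or below that level, the fold is given as a lower bound against it ("at least"). For arrays, the number of arrays limits the precision: the median standard error of a log2 change was 0.08.

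Before the data were examined, 22 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists cover Notch targets, Notch pathway machinery, secretory lineage transcription factors, markers of goblet, enteroendocrine, Paneth, absorptive and tuft cells, intestinal stem cell and Wnt target genes, proliferation, CDK inhibitors, p53 targets, neddylation machinery, ER stress response, cholesterol synthesis, interferon response, hypoxia and glycolysis, mucin O-glycosylation enzymes, ribosome biogenesis, and markers of fibroblasts, leukocytes and endothelium. They were written from textbook knowledge and were not chosen on these samples. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, adjusted over the 22 lists. With an estimated correlation, camera also uses the few residual degrees of freedom of the 6 arrays, which raises p even where the correlation is low. Camera asks whether the genes of a list moved more than the other genes did, whereas fry asks whether they moved, on balance, in 1 direction.

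Genes were named by rule: the 10 largest rises and the 10 largest falls among genes that passed with no overlap between the groups; from each list up to 3 members that passed, those with the smallest p, or the member with the smallest p where none passed; and, whatever their result, HES1, ATOH1, MUC2, KLF4, CDKN1A, SPDEF, LGR5, MYC and NOTCH1. This gave 62 genes. Any gene named beyond the rule was chosen after its values were seen, and the text says so.

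The alternatives tried were no filter on dim probe sets, a stricter filter (the lowest 60%), quantile normalization, median centring, a floor at the 20th percentile of each array, log2(value + 32), the mean of all probe sets of a gene, probe sets in place of genes, leaving out probe sets of the _x_at design, eBayes with trend and robust options, array weights, the replicate number as a block, the 10,896 probe sets with the smallest spread within groups, and leaving out each array in turn. After the data were seen, 2 more were added: centring each array on its 9 hybridisation control probe sets, and keeping only genes above the Bacillus control level in at least 1 group (12031 genes). Single values with 3 arrays per group were compared by a two-sided exact permutation test, which cannot give a p below 0.1 here.

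The fit was tested on simulated data for the comparison of CompE with DMSO, with 14308 genes of which 200 were changed and 20 others formed a list shifted by a log2 change of 0.5. Of the 200, it recovered 50% of the genes with a true log2 change of 0.5, 78% of those with 1, 80% of those with -1 and 94% of those with 2. Of 167 genes called, 151 were among the 200, 8 belonged to the shifted list and 8 were false (4.79%), and 0 of 20 unchanged lists were called. The simulated genes were drawn independently of each other. The result for the unchanged lists therefore says nothing about false calls of lists whose genes are correlated. Genomic positions are not reported here, because the array values carry no genome build.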

Results

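The transcriptome of LS174T cells was profiled after 48 h in CompE at 250 nM or in the vehicle DMSO, with 3 cultures and 3 arrays per condition. The title of the series concerns NOTCH1 and neddylation in T cell acute lymphoblastic leukaemia. These 6 arrays address a narrower question, namely how a colon line with a secretory character responds to CompE alone. Median probe set intensities lay between 36.9 and 38.6 on the 6 arrays, and the highest intensities between 16487 and 17949. Over the 32767 probe sets past the filter, arrays of the same group correlated at r = 0.987 to 0.988 (6 pairs). Arrays of different groups correlated at r = 0.981 to 0.985 (9 pairs). These correlations are across probe sets, which are not independent replicates. The first principal component held 38.9% of the variance and separated the conditions. The median standard deviation within groups was 0.10 on the log2 scale.

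Control features of the arrays also differed between the groups. The ratio of 3' to 5' probe sets of ACTB, a measure of RNA integrity and amplification, was 1.44 ± 0.0201 in DMSO and 1.51 ± 0.0193 in CompE (mean ± SD, n = 3 each; exact permutation p = 0.1, the smallest possible). The same ratio for GAPDH was 0.968 ± 0.0106 and 0.946 ± 0.0264 (exact permutation p = 0.3). The bacterial transcript bioB, which is added in equal amount before hybridisation by the standard protocol, was 0.20 log2 units brighter in CompE (1.15-fold; exact permutation p = 0.1).

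CompE raised ATOH1, the transcription factor that commits intestinal progenitors to secretory fates, 6.13-fold, from an intensity of 94.1 ± 13.2 in DMSO to 574 ± 53.7 (mean ± SD, n = 3 arrays; log2 change 2.61 ± 0.13 SE, adjusted p = 0.000892). It lowered OLFM4, a secreted glycoprotein of intestinal stem cells and a Notch target, 6.08-fold, from 1923 ± 105 to 316 ± 17.5 (log2 change -2.60 ± 0.07, adjusted p = 0.000253). HES1, the transcriptional repressor that Notch induces, fell 2.81-fold from 811 ± 58.2 to 289 ± 29.2 (log2 change -1.49 ± 0.10, adjusted p = 0.00198). Its other probe set gave -1.53. Among the largest rises were the Notch ligand gene DLL4 (3.49-fold) and RETNLB, which encodes a goblet cell secreted protein (4.27-fold). DEFA6, an alpha-defensin gene of Paneth cells, rose 3.63-fold. NEUROG3, the transcription factor of endocrine progenitors, rose from 16.2 ± 4.03, below the level of the Bacillus controls, to 61.5 ± 3.54. The increase was at least 1.35-fold over that level (adjusted p = 0.00605).

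The remaining large rises were in LINC00261, a long non-coding RNA (4.88-fold), ANXA13, an annexin gene (4.44-fold), and KLK12, a kallikrein peptidase gene (4.0-fold). OR51E1, an odorant receptor gene, rose 3.64-fold, and ADGRB1, an adhesion receptor gene, at least 2.74-fold. The largest falls besides OLFM4 and HES1 were in IGFL2, which encodes a growth factor-like secreted protein (log2 change -2.32), and in EMP1, an epithelial membrane protein gene (-1.79). The 2 other probe sets of EMP1 disagreed in size (-1.96 and -0.15), and 1 of them passed. The chemokine gene CXCL8 (-1.57), the annexin gene ANXA1 (-1.51) and the cytokine gene IL33 (-1.48) followed. The rule also took the chemokine gene CCL20 (at least 3.32-fold lower), NALT1, a non-coding RNA named for its association with NOTCH1 (at least 1.97-fold), and the metalloprotease gene ADAM19 (at least 1.47-fold). These 3 lay at or below the Bacillus control level in CompE. Their rank is therefore uncertain, and so is the place of NALT1 and ADAM19 among the 10 largest falls. The bound of CCL20 still exceeded the 2.97-fold fall of CXCL8. Adjusted p-values of these 20 genes ran from 0.000253 to 0.0156. The call of NALT1, the gene with that highest value, ended without DMSO replicate 1, 2 or 3 and without CompE replicate 2 (highest adjusted p 0.0671).

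**Figure D1:**
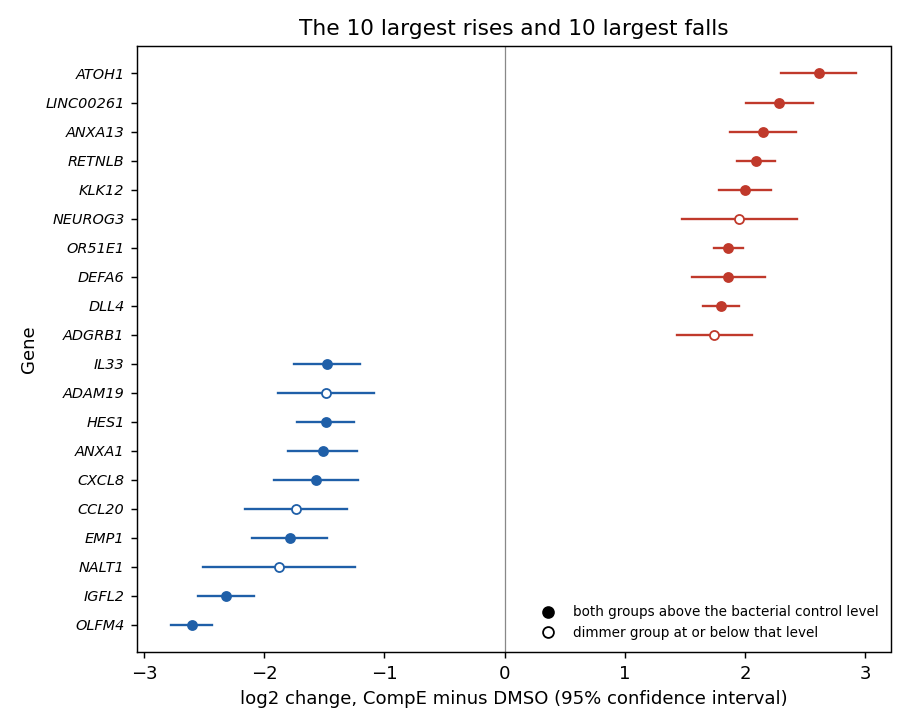
The 10 largest rises and the 10 largest falls, as log2 change of CompE minus DMSO on the horizontal axis with 95% confidence intervals from the limma fit of 3 arrays per group. Open circles mark genes whose dimmer group lay at or below the Bacillus control level, where the size of the change and the rank are uncertain. ATOH1 at 2.61 and OLFM4 at -2.60 lie at the ends of the range.

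Of 14308 genes tested, 653 rose and 368 fell, and 93 changed at least 2-fold (63 higher, 30 lower). Most of the 1021 changes were small: 701 were under 1.5-fold, and the median size was 0.45 log2 units. Groups did not overlap for 32.2% of the genes, where chance gives 10%. With 1 array left out the count of changed genes was 381, 292 and 300 without DMSO replicates 1, 2 and 3, and 252, 429 and 519 without CompE replicates 1, 2 and 3. The count at 2-fold then lay between 73 and 95. The predominance of rises (64.0%) depended on the scaling. With each array centred on its hybridisation controls, the median change of all genes moved from 0.02 to -0.09, and 384 genes rose while 1130 fell (25.4% rises). At 2-fold there were then 45 rises and 53 falls. That centring subtracts 1 constant per array, although the shift of the controls ran from 0.20 log2 units for bioB to -0.03 for cre.

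Genes of the Notch pathway moved in both directions. Of 16 Notch targets tested, 3 fell (OLFM4, HES1 and NRARP), 2 rose (LFNG and NOTCH1 itself) and 11 did not pass. When adjusted over the list alone, 4 fell and 2 rose (6 negative and 2 positive at an unadjusted p under 0.05). LFNG, which encodes a glycosyltransferase that modifies Notch receptors, rose 2.42-fold from 448 ± 7.73 to 1083 ± 38.3 (n = 3, adjusted p = 0.000512). NOTCH1 rose 1.72-fold, from 514 ± 10.5 to 882 ± 25.2 (n = 3, adjusted p = 0.00173). NRARP, a feedback regulator of Notch named after its values were seen, fell by 0.32 log2 units (adjusted p = 0.0418). MYC, a Notch target in T cell leukaemia, was at 3583 ± 41.0 in DMSO and 3177 ± 180 in CompE, a log2 difference of -0.18 that did not pass (adjusted p = 0.140). As a list, the targets had a mean log2 change of -0.21 (camera adjusted p = 0.151; adjusted p = 0.466 with an estimated correlation; fry adjusted p = 0.0609). Restricted to the 10,896 least variable probe sets, the mean was -0.14 with an adjusted p of 0.0441, the lowest of the alternatives, which reached up to 0.466.

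Of 20 genes of the Notch pathway machinery tested, 2 rose, 0 fell in the limma fit and 18 did not pass. Adjusted over the list alone, 3 rose and 0 fell, and at an unadjusted p under 0.05 there were 3 positive and 1 negative changes. Both were ligand genes. DLL4 went from 104 ± 5.61 to 364 ± 13.04. DLL1 rose 2.55-fold from 439 ± 2.44 to 1122 ± 105 (n = 3, adjusted p = 0.00164), although its other, dimmer probe set gave -0.02. The list's mean log2 change was 0.19 (camera adjusted p = 0.193; adjusted p = 0.466 with an estimated correlation; fry adjusted p = 0.00545). With the 10,896 least variable probe sets its adjusted p was 0.0310, within a range over the alternatives of 0.00545 to 0.466.

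Most transcription factors of the secretory lineage that were tested rose, although the list was not called with an estimated correlation (adjusted p = 0.0701). Of 13 tested, 9 rose, 0 fell in the limma fit and 4 did not pass. Adjusted over the list alone, 10 rose and 0 fell (11 positive and 0 negative at an unadjusted p under 0.05). Besides ATOH1 and NEUROG3, SOX4, a transcription factor of endocrine and tuft precursors, rose 1.75-fold from 3549 ± 108 to 6193 ± 39.6. CREB3L4, of the family that adapts cells to secretion, rose 1.59-fold. SPDEF and KLF4, both needed for goblet cell maturation, rose little: SPDEF 1.27-fold (adjusted p = 0.0325) and KLF4 1.25-fold (adjusted p = 0.0242). The other probe sets disagreed for SOX4 (-0.05 to 1.4 over 5) and for SPDEF (-0.26 to 0.86 over 4), in each case 1 of them in direction. The mean log2 change of the list was 0.65 (camera adjusted p = 2.48e-08 with the preset correlation). When 1 array was left out, the call of KLF4 ended whichever array it was (highest adjusted p 0.0973, without CompE replicate 1). Its log2 change stayed between 0.29 and 0.34 in these fits. The call of SPDEF ended in each case but without DMSO replicate 1 (highest 0.116, without CompE replicate 1). Both calls also ended with no filter on dim probe sets.

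Most goblet cell markers rose as well, with 13 of 19 tested higher, 0 lower in the limma fit and 6 that did not pass. Here too the list was not called with an estimated correlation (adjusted p = 0.104). There were 15 higher and 1 lower adjusted over the list alone, as at an unadjusted p under 0.05. MUC2, the gel-forming mucin gene of the intestine, rose 2.07-fold from 481 ± 24.5 to 993 ± 38.6 (n = 3; log2 change 1.05 ± 0.06, adjusted p = 0.00164). FCGBP, which encodes a mucus protein that binds immunoglobulin, rose 2.76-fold from 344 ± 12.2 to 948 ± 12.2. SPINK4, a peptidase inhibitor gene of goblet cells, rose 2.75-fold from 832 ± 13.2 to 2295 ± 124. TFF1, named after its values were seen as the member with a decrease over the list alone, changed by -0.37 (adjusted p = 0.0508 over all genes). The list's mean log2 change was 0.62 (camera adjusted p = 4.67e-10 with the preset correlation; fry adjusted p = 0.000135).

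**Figure D2:**
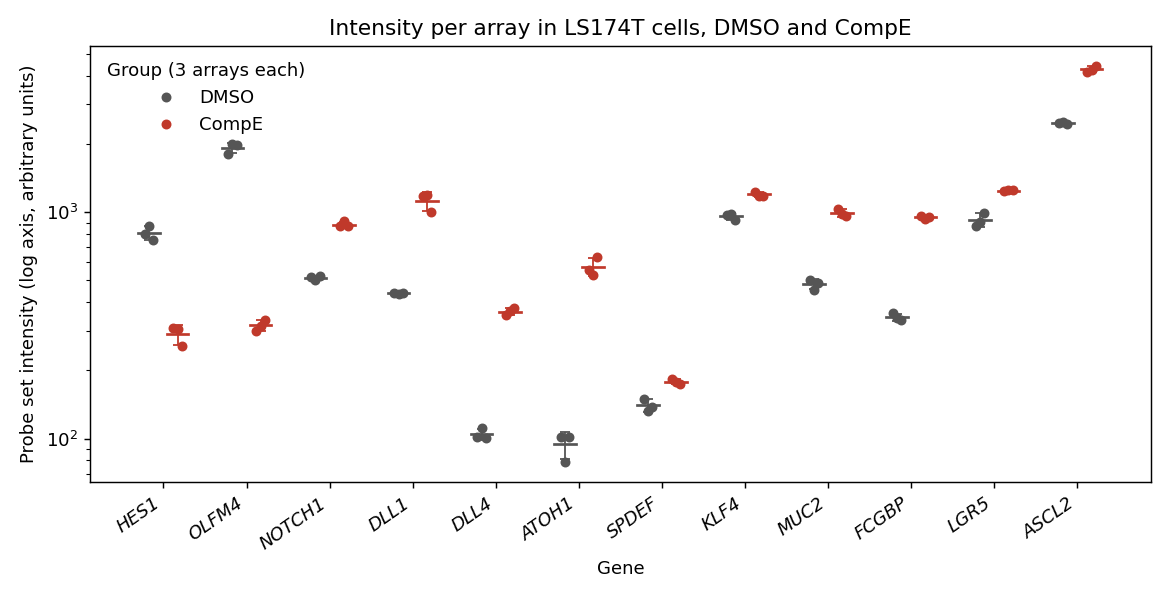
Probe set intensity of 12 genes on each array, on a log axis in arbitrary units, for 3 DMSO arrays (grey) and 3 CompE arrays (red); bars give the mean and the SD. HES1 and OLFM4 were lower in CompE on all 3 arrays than on any DMSO array, and the other genes were higher.

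Markers of other intestinal cell types gave mixed results. The enteroendocrine list held 24 genes, of which 21 had a probe set with 1 gene and only 7 passed the filter on dim probe sets. Of these 7, 2 rose and 0 fell in the limma fit (4 rose and 0 fell adjusted over the list alone, and at an unadjusted p under 0.05). They were NEUROG3, which is also on the list of transcription factors, and ISL1, a transcription factor of endocrine cells (1.22-fold, adjusted p = 0.0367). The list's mean was 0.40 (camera adjusted p = 0.0937; adjusted p = 0.416 with an estimated correlation; fry adjusted p = 0.00524). The adjusted p was under 0.05 in 6 of 22 alternatives, among them 0.00818 for genes above the Bacillus control level and 0.0284 without DMSO replicate 2, in a range of 0.00524 to 0.416. Of 6 Paneth cell markers tested, 3 rose and 1 fell, or 3 and 3 adjusted over the list alone and at an unadjusted p under 0.05. Their camera adjusted p was 0.606 (adjusted p = 0.762 with an estimated correlation; fry adjusted p = 0.000135, direction up). Those that rose were DEFA6, PLA2G2A, a secreted phospholipase gene (1.64-fold), and DEFA5, another alpha-defensin gene named after its values were seen (2.76-fold, adjusted p = 0.0120). The member that fell was the trypsinogen gene PRSS2 (log2 change -0.97, adjusted p = 0.00259). Its probe set shares probes with near-identical trypsinogen genes, so that its identity is uncertain. The call of ISL1 ended with no filter and whichever array was left out (highest adjusted p 0.128, without CompE replicate 1).

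Of 16 absorptive enterocyte markers tested, 2 fell and 0 rose in the limma fit (3 fell and 1 rose adjusted over the list alone, and at an unadjusted p under 0.05). They were DPP4, a brush border peptidase gene (log2 change -0.71, adjusted p = 0.00805), and CA2, a carbonic anhydrase gene (-0.60, adjusted p = 0.0301). The call of CA2 ended with no filter and whichever array was left out (highest adjusted p 0.102, without DMSO replicate 2). The list's mean was -0.12 (camera adjusted p = 0.156; adjusted p = 0.444 with an estimated correlation; fry adjusted p = 0.00543). With probe sets in place of genes it was -0.19 with an adjusted p of 0.0166, in a range of 0.00543 to 0.444. Of 13 tuft cell markers, 10 had a probe set with 1 gene and only 3 passed the filter on dim probe sets. None of these 3 passed in the limma fit (0 at an unadjusted p under 0.05), and the list's camera adjusted p was 0.606. The smallest p belonged to ALOX5, a lipoxygenase gene at or below the Bacillus control level in both groups (adjusted p = 0.497).

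Intestinal stem cell and Wnt target genes rose in part. Of 17 tested, 6 rose, 0 fell in the limma fit and 11 did not pass. Adjusted over the list alone, 6 rose and 1 fell (7 positive and 2 negative at an unadjusted p under 0.05). SMOC2, a matrix protein gene of crypt base cells, rose 2.29-fold from 419 ± 9.97 to 959 ± 43.7 (n = 3, adjusted p = 0.000699). RGMB, which encodes a BMP co-receptor, rose 1.99-fold to 4348 ± 116. ASCL2, a transcription factor of intestinal stem cells, rose 1.73-fold to 4291 ± 137. LGR5, the R-spondin receptor gene of crypt base stem cells, rose 1.35-fold (adjusted p = 0.0194). AXIN2, named after its values were seen as a common readout of Wnt signalling, changed by 0.06 (adjusted p = 0.543). OLFM4, which is expressed in the same crypt cells but is on the list of Notch targets, fell. The list's mean was 0.38 (camera adjusted p = 0.000496; adjusted p = 0.104 with an estimated correlation). LGR5 lost its call with no filter and when any array but DMSO replicate 3 was left out (highest adjusted p 0.0806, without DMSO replicate 2).

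Proliferation genes showed no shift that could be detected: 0 of 26 tested passed in the limma fit (2 positive at an unadjusted p under 0.05). Their mean log2 change was 0.02 (camera adjusted p = 0.911). RRM2, a ribonucleotide reductase gene and the member with the smallest p, differed by 0.15 (adjusted p = 0.126). Of 4 CDK inhibitor genes, 0 passed (2 positive at an unadjusted p under 0.05; camera adjusted p = 0.552). CDKN1B, which encodes p27, was closest at 0.19 (adjusted p = 0.0959). CDKN1A, which encodes p21, was at 1713 ± 217 in DMSO and 1580 ± 108 in CompE (adjusted p = 0.586). Neddylation machinery, the other pathway of the series' title, had 0 of 21 genes past the limma threshold (1 positive and 1 negative at an unadjusted p under 0.05) and a mean of 0.04 (camera adjusted p = 0.606). DCUN1D2, a gene of a cullin neddylation cofactor, was the closest at 0.37 (adjusted p = 0.0793). Centred on the hybridisation controls, the means of the proliferation and neddylation lists were -0.09 and -0.07, beside a median of all genes of -0.09.

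Stress and growth lists had smaller mean changes, all below 0, and none of them was called with an estimated correlation. The 21 ER stress genes had a mean of -0.15 (camera adjusted p = 0.000592; adjusted p = 0.444 with an estimated correlation). Of these, 3 fell, or 4 adjusted over the list alone (5 negative and 1 positive at an unadjusted p under 0.05). The 3 were ATF3, a stress-induced transcription factor gene (-0.82), TRIB3, a pseudokinase gene (-0.30), and HSPA5, which encodes the chaperone BiP (-0.20). The 18 hypoxia and glycolysis genes had a mean of -0.13 (camera adjusted p = 0.000672; adjusted p = 0.529 with an estimated correlation; fry adjusted p = 0.1003). In that list 3 fell, namely SLC2A1, a glucose transporter gene (-0.59), ANKRD37, a hypoxia-induced gene (-0.55), and PDK1, a pyruvate dehydrogenase kinase gene named after its values were seen (-0.29). ADM, the gene of the peptide adrenomedullin, rose (0.63). In all, 5 fell and 1 rose adjusted over the list alone (8 negative and 1 positive at an unadjusted p under 0.05). Of 20 ribosome biogenesis genes 0 passed in the limma fit (0 positive and 5 negative at an unadjusted p under 0.05), and 18 had values below 0. Their mean was -0.11 (camera adjusted p = 0.000496; adjusted p = 0.104 with an estimated correlation). MRTO4, a ribosome assembly factor gene, had the smallest p (-0.26, adjusted p = 0.0508) and passed in 9 of 21 alternatives. Among 18 p53 targets 1 fell, the death receptor gene FAS (-0.48), and 1 rose, the oxidoreductase gene TP53I3 (0.69), with 3 lower and 2 higher adjusted over the list alone (7 negative and 2 positive at an unadjusted p under 0.05).

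The p53 list's mean was -0.11 (camera adjusted p = 0.0481; adjusted p = 0.466 with an estimated correlation; fry adjusted p = 0.101). Its call ended without DMSO replicate 1 or 3 and without CompE replicate 2 or 3 (adjusted p = 0.112, 0.0671, 0.0629 and 0.0810). It also ended with the stricter filter, trend and robust options, array weights and arrays centred on hybridisation controls (0.0640, 0.0548, 0.0617 and 0.0776), and stood in 13 of 23 alternatives. With the 10,896 least variable probe sets the ER stress and hypoxia lists had adjusted p-values of 0.0556 and 0.0674. Over all alternatives these ran from 5.95e-05 to 0.444 and from 2.61e-05 to 0.529. Among the genes of these lists, the calls of TRIB3 and HSPA5 ended whichever array was left out (highest adjusted p 0.0933 and 0.143). Their log2 changes hardly moved over these fits (-0.31 to -0.27 and -0.21 to -0.20). The calls of ATF3, ANKRD37 and SLC2A1 ended in each case but without CompE replicate 2 (highest 0.109, 0.0708 and 0.1001). The call of ADM ended in each case but without CompE replicate 3 (highest 0.1002), that of TP53I3 in each case but without DMSO replicate 3 (highest 0.0914), and that of FAS without DMSO replicate 3 or CompE replicate 1 (highest 0.0585). With no filter, all of these calls except that of FAS ended.

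Enzymes of mucin O-glycosylation, which builds the sugar chains of mucins, went both ways: of 17 tested, 1 rose, 2 fell and 14 did not pass (1 rose and 4 fell adjusted over the list alone, and 2 were positive and 6 negative at an unadjusted p under 0.05). GCNT3, the gene of a core-branching enzyme of mucin glycans, fell 1.88-fold from 1390.5 ± 114 to 738 ± 59.3 (n = 3, adjusted p = 0.00585). ST3GAL1, a sialyltransferase gene, fell (-0.74, adjusted p = 0.0346), and ST6GALNAC1, the sialyltransferase gene also counted among the goblet cell markers, rose (0.43, adjusted p = 0.0170). The list's mean (-0.13) and median (0.01) differed in sign (camera adjusted p = 0.263, direction down). Of 16 cholesterol synthesis genes 1 rose, the sterol desaturase gene SC5D (0.26), and 0 fell in the limma fit (0 negative at an unadjusted p under 0.05). The counts adjusted over the list alone were the same, and camera gave an adjusted p of 0.556. Of 15 interferon response genes 0 passed (0 positive and 1 negative at an unadjusted p under 0.05; camera adjusted p = 0.974). IFITM1, a membrane protein gene induced by interferon, was closest (-0.14, adjusted p = 0.165). The calls of ST3GAL1 and SC5D ended whichever array was left out (highest adjusted p 0.109 and 0.121), and that of ST6GALNAC1 in each case but without DMSO replicate 2 (highest 0.0774). All 3 also ended with no filter.

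Markers of cell types that a pure line should lack gave few changes. The Bacillus control level was exceeded in at least 1 group by 6 of 8 fibroblast, 4 of 8 leukocyte and 1 of 4 endothelial markers. Among 8 fibroblast markers FAP, a cell surface peptidase gene, fell from 58.9 ± 8.04 to 38.6 ± 3.80, by at least 1.28-fold against the Bacillus control level (adjusted p = 0.0443). Its call ended with no filter and whichever array was left out (highest adjusted p 0.116, without DMSO replicate 2). None of 8 leukocyte and none of 4 endothelial markers passed in the limma fit (1 positive and 1 negative, and 1 negative, at an unadjusted p under 0.05). CD2, a T cell surface protein gene, and KDR, a VEGF receptor gene, had the smallest p in these lists. Both lay below the Bacillus control level in both groups. Camera adjusted p-values were 0.263 for fibroblast, 0.746 for leukocyte and 0.564 for endothelial markers.

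**Figure D3:**
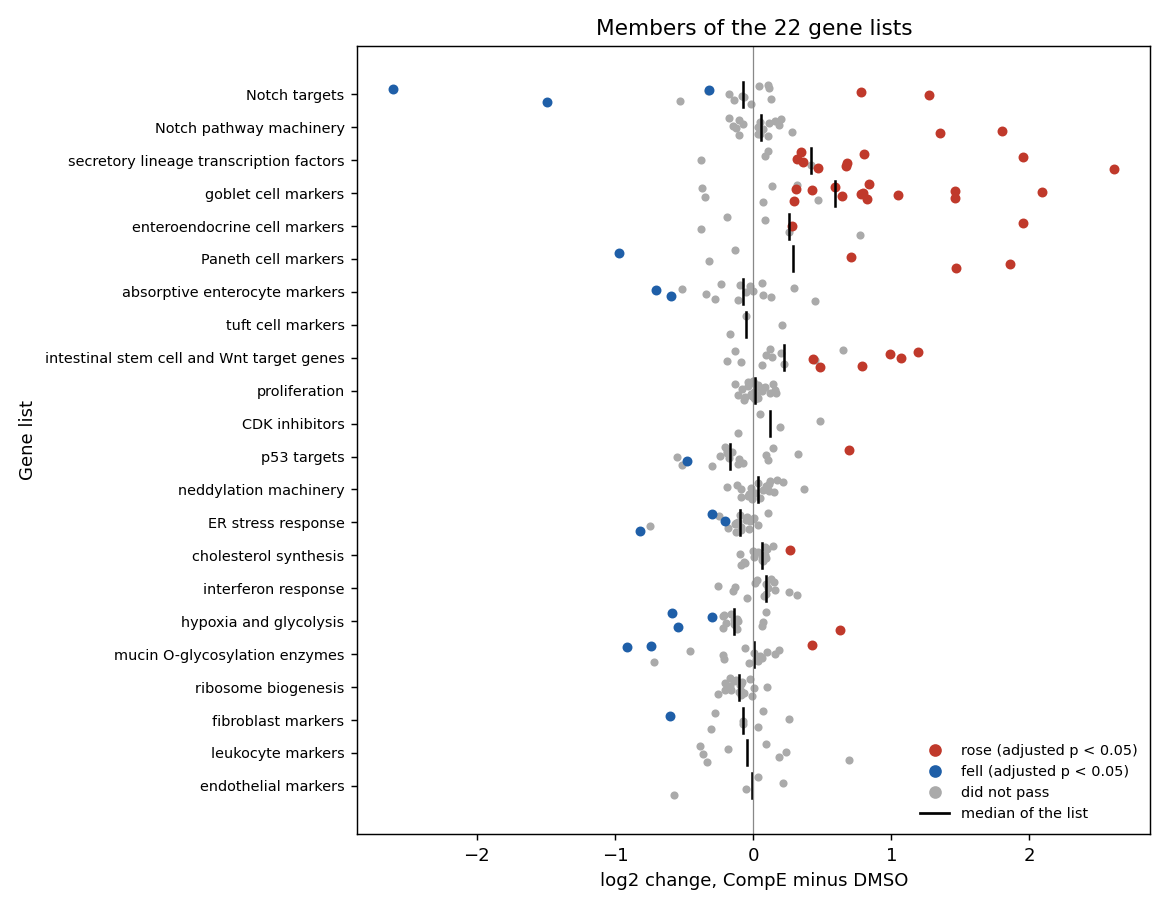
Log2 change of CompE minus DMSO for each tested member of the 22 gene lists, 1 line of points per list; red points rose, blue points fell and grey points did not pass, and the black tick is the list's median. The medians of the secretory transcription factors (0.42) and of the goblet cell markers (0.60) stand to the right of 0.

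Of the 22 lists, camera called 7 (3 higher, 4 lower) with the preset correlation and 0 with an estimated correlation. With the estimated correlation the lowest adjusted p was 0.0701 and 4 lists had an unadjusted p under 0.05. Fry called 9. Among the 7, the estimated correlation ran from 0.106 to 0.587 for the goblet, p53, ER stress and hypoxia lists. For secretory transcription factors (-0.0645), stem cell and Wnt genes (0.00513) and ribosome biogenesis (-0.00236) it lay below the preset 0.01. The higher p of the secretory, stem cell and ribosome lists thus cannot come from a higher correlation. In this setting camera refers its statistic to the few residual degrees of freedom of the 6 arrays, not to the number of genes. That raises p for every list. For the goblet, p53, ER stress and hypoxia lists the higher correlation raises it further. Adjusted over the list alone, the lists with 0 genes past the limma threshold (tuft cell markers, proliferation, CDK inhibitors, neddylation machinery, interferon response, ribosome biogenesis, leukocyte and endothelial markers) also had 0, and fibroblast markers had 1.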

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

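In this part, the centring on hybridisation controls and the counts of changed genes over other splits of the arrays were chosen as tests only after the result was seen.

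Signals outside the genes tested differed between the groups in the array controls. The hybridisation controls bioB, bioC and bioD, bacterial transcripts that the standard protocol adds in equal amount to each labelled sample, were 0.20, 0.17 and 0.0609 log2 units brighter in CompE than in DMSO (n = 3 each; exact permutation p = 0.1 for each, the smallest possible). The phage control cre, the brightest of them, differed by -0.03 (exact permutation p = 0.7).

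This bears on the pattern that more genes rose than fell (64.0% of the changed genes), for which unequal scaling of the arrays is a candidate explanation. Under quantile normalization and median centring the share of rises was 59.5% and 58.6%, above the bound fixed in advance, but that bound was wrong as a test: both scalings, like that of the authors, hold the bulk of the genes in place, and centring on the hybridisation controls gave 25.4%. If the shift in the controls acted on all features of like brightness, genes near bioB should share it; the median change of the 2015 genes within 0.5 log2 units of bioB was 0.0208 (bootstrap 95% interval 0.01 to 0.03) against 0.20 for bioB. The authors' normalization sets gene medians close to 0 whatever the controls do, so this value decides nothing either. A real excess of induced genes under CompE, unequal scaling and a difference in the amount of labelled RNA relative to the controls therefore cannot be told apart, since no feature on the array fixes the scale independently of these controls.

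Some probe sets without a single gene name, which the comparison did not use, also changed. Of 5805 such probe sets tested, 11 rose and 5 fell, 8 and 2 of them at least 2-fold. That share is far below the 7.14% of the genes tested that changed. Several of the rises were probe sets given to the same 2 genes (C1QTNF3-AMACR and AMACR), so the counts are not of separate genes. The largest rise was in a probe set that the annotation gives to more than 1 gene, so that no gene is named (log2 change 1.32, adjusted p = 0.0183).

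Splitting the 6 arrays into 3 and 3 allows 10 splits, too few for a share under 0.05; only 1 of the 10, the real one, reached its own count in each case. The real split gave 1021 changed genes, 93 changed at least 2-fold and 7 gene lists by camera, and the highest values of the 9 others were 0, 0 and 4. At an unadjusted p under 0.05, the other splits gave between 385 and 818 genes in limma and the real one 3511. Each other split mixes both conditions in both groups. Any difference between the conditions then adds to the spread within groups and lowers the counts by construction. The 9 splits therefore do not show what the absence of an effect would give.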

How the results depend on the processing

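In this part, the centring on hybridisation controls and the restriction to genes above the Bacillus control level were chosen only after the data had been seen; the other alternatives were planned.

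No named gene changed direction under any alternative in which it was tested. Of the 52 that passed, 34 also passed in all 6 fits with 1 array left out and in all other settings apart from the replicate block, and 17 passed in 3 or fewer of those 6 fits. A fit with 1 array fewer has less power by construction, so a lost call alone does not show dependence on that array. With the replicate block 23 of the 52 calls ended, with no filter 16, with the mean of all probe sets 6, with median centring 4, with probe sets in place of genes 4 and with quantile normalization 1. KLF4, SPDEF, LGR5, ISL1 and SC5D lost theirs with arrays centred on hybridisation controls, a scaling under which MYC passed (adjusted p 0.0256, in a range over its alternatives of 0.00192 to 0.290). Of the 10 that did not pass, MRTO4 passed in 9 alternatives, MYC, CDKN1B, DCUN1D2 and IFITM1 in 3 each and RRM2 in 2.

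The count of changed genes depended on the settings. It was 363 with no filter, 1751 with the stricter filter and 2254 with trend and robust options (the causes were not tested). Restricted to the 10,896 least variable probe sets it was 2930, of which 684 were among the 1021; that selection favours small variances by construction. With 1 array left out it ran from 252 to 519, with fewer samples by construction. The replicate numbers did not pair the cultures: deviations of same-numbered arrays correlated at 0.02, -0.10 and -0.02, none was best with its own number, and the replicate block, which spends degrees of freedom, gave 102 changed genes (99 shared), 62 at 2-fold and 7 lists. The count at 2-fold was 42 with log2(value + 32), which compresses dim genes, 141 with probe sets in place of genes, which counts genes repeatedly, and 27 with the 10,896 probe sets; with other settings it stayed within 1.5 times of 93, but on hybridisation controls falls outnumbered rises (53 and 45).

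Camera with an estimated correlation called 0 lists (4 at an unadjusted p under 0.05; fry called 9). The goblet cell markers (mean 0.62, which this setting cannot change) had an adjusted p of 0.104 there, the highest over their alternatives (lowest 3.17e-35), and the Notch targets were called only with the 10,896 probe sets (mean -0.14, adjusted p 0.0441; highest 0.466; the cause was not tested). Camera's direction, which is relative to the other genes, turned only for lists not called in the first place, and the cause was not tested. Mean log2 changes where it turned were: for the interferon response -0.000231 with no filter, 0.0302 with the stricter filter, 0.0570 with trend and robust options, 0.0689 with array weights, 0.00822 with the 10,896 probe sets, and 0.0299 above the Bacillus control level; with 1 array left out they ran from 0.0332 to 0.0855, and the direction turned in 3 of the 6 fits. For proliferation they were 0.00402 with median centring, 0.0121 without _x_at probe sets, 0.0158 with array weights, 0.00870 with the 10,896 probe sets, and -0.0926 on hybridisation controls; with 1 array left out they ran from 0.00502 to 0.0264, and the direction turned in 2 of the 6 fits. Cholesterol synthesis gave 0.00610 with the mean of all probe sets, -0.00842 with probe sets and -0.0664 on hybridisation controls; Paneth cell markers gave 0.0929 with probe sets and -0.130 with the 10,896; neddylation machinery gave 0.0129 with the 10,896 and -0.0668 on hybridisation controls. Leukocyte markers gave -0.117 on hybridisation controls and, with 1 array left out, -0.101 to 0.109 (turned without DMSO replicate 2, at 0.0463, and without CompE replicate 2). Endothelial markers gave -0.261 to 0.0784 with 1 array left out (turned without DMSO replicate 2).

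Signal over background limits the dim genes: 12031 of the 14308 genes lay above the Bacillus control level in at least 1 group, and restricted to them 1531 changed.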

Other observations

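In this part, the test of whether uncalled Notch targets were too dim was chosen only after its result was seen; the lists of ERK output and NF-kB target genes were written after the genes that prompted them had been seen, without those genes and before the lists' own values were.

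Outside the gene lists, the genes below were picked after their values were seen, because they changed, and say nothing about any group of genes as a whole. EREG, which encodes an EGF family ligand, fell 2.33-fold (log2 change -1.22 ± 0.08 SE, adjusted p = 0.00194), the early response transcription factor gene FOS fell 2.30-fold (-1.20 ± 0.11, adjusted p = 0.00515), and ETV4, an ETS transcription factor gene induced by ERK signalling, fell 2.55-fold (-1.35 ± 0.05, adjusted p = 0.000512). NOX1, the superoxide-producing oxidase gene of colon epithelium, fell 2.52-fold, and the chemokine gene CXCL1 fell 2.45-fold, beside CCL20 and CXCL8. The forkhead transcription factor gene FOXQ1 fell 2.57-fold and the protease gene CTSE fell 2.52-fold. Among the rises outside the lists was HEPACAM2, an adhesion molecule gene, at 2.68-fold (1.42 ± 0.05, adjusted p = 0.000512). All of these were limma comparisons of 3 arrays against 3.

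The falls of EREG, FOS and ETV4 prompted the hypothesis that output of the ERK pathway was lower in CompE. A list of ERK output genes without those already seen had 21 genes tested, of which 6 fell (DUSP6, IER3, EPHA2, FOSL1, HBEGF and SPRY2, by 0.33 to 0.80 log2 units) and 1 rose (EPHA4, 0.34). Its mean log2 change was -0.19, with an unadjusted camera p of 0.000143 and an unadjusted p of 0.0376 with an estimated correlation. The 22 fixed lists were judged by adjusted p. With an estimated correlation 4 of them had an unadjusted p under 0.05 and were not called. The values of the ERK list may reflect lower ERK output, but they measure transcripts of genes that other pathways also control. The decrease was small, and no measurement of ERK activity was analysed here.

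The falls of chemokine genes prompted a second hypothesis, lower output of NF-kB. Of 20 NF-kB target genes tested, after leaving out those already seen, 2 fell (CXCL2 by 1.02 and CXCL3 by 0.69 log2 units), both chemokine genes themselves. The mean was -0.16, with an unadjusted camera p of 0.00651 and an unadjusted p of 0.0644 with an estimated correlation. A shift of the pathway as a whole thus stays open, and a change limited to chemokine genes could also give these values.

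HES1 and OLFM4 fell while most Notch targets did not pass (6 of 16 were negative at an unadjusted p under 0.05), a pattern for which technical explanations were tested first. For uncalled members well above background, the values argue against 2-fold falls hidden by low signal. Of the 11 uncalled members, 81.8% (9) lay above the Bacillus control level, and the 95% interval of 10 of the 11 excluded a 2-fold fall. Among the 10, HEY1 lay below that level and HEYL barely above it (mean log2 5.53 against 5.51). A fall at background could not show, so the intervals of HEY1 and HEYL decide nothing. NOTCH3 also lay below it. Smaller falls could have been missed. The called target NRARP fell by only 0.32 log2 units. The simulation recovered 50% of genes with a true log2 change of 0.5. It called 167 genes where the real comparison called 1021, so its adjusted threshold was stricter. Its 50% is therefore not the rate for these targets. HES4, named after its values were seen, changed by -0.53 without passing (limma adjusted p = 0.0508). A poorly chosen probe set is also argued against for the 6 uncalled members with another probe set. Of these 6, 0 had one that passed with a decrease in limma. The other uncalled members, among them HES4, HES5 and HEY1, had no second probe set past the filter. For them this explanation stays open. The list mixes targets known from T cells with those of intestine, and a response specific to the cell type may account for the pattern; these arrays hold 1 line and cannot test it.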
